A study of Mus musculus with 3 samples.

How the data were processed

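CUT&RUN libraries were made from mouse retina (C57Bl6/J) at embryonic day 14, 2 with an Atoh7 antibody and 1 with IgG, per the labels. The groups were taken from the sample titles. The labels do not say whether the Atoh7 libraries came from separate animals. Reads were processed by the authors with Bowtie2 2.3.5, SAMtools, Picard 2.0.1, MACS2 2.2.7.1 and bedtools on the mm10 build, per the submitters' processing notes, which give no order or settings. The deposited table holds 3668 peaks as chromosome, start, end, width and name, per the file headers, with coordinates counted from 1. It gives no enrichment, p-value or pileup and no value per library.

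Every peak name begins with Atoh7_R1, and the numbers in the names rise along the genome to 7185, so that 3517 numbers are absent and 51.1% are present. The step that removed the absent numbers, and any use of the replicate 2 library or of IgG in it, is not given in the sources used here. Read depth per library is unknown, so no value could be weighted by depth, and intervals on shares cover counting of peaks or genes only. No peaks of the list overlap each other.

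Genes came from a RefSeq table of GRCm38.p6, the assembly that mm10 names, with 49554 genes on chromosomes 1 to 19 and X, 21631 of them protein-coding. The table gives the start and end of each gene but neither strand nor exons, and no genome sequence was used here. Before the data were examined, the tests, 15 gene lists and the rule for named genes had been fixed for transcription start sites, exons and introns, E-box hexamers and peak strength. Start sites were replaced by gene ends, meaning either end of an annotated gene, and exon and intron were merged as gene body. The E-box tests were not run. Peak width took the place of peak strength in the test at gene ends, in the choice of a stricter set of peaks and in the rule for named genes, a choice made after the data were seen. Width is not a measure of occupancy.

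Positions were tested on the 3662 peaks of chromosomes 1 to 19 and X, leaving out 5 peaks on the mitochondrial chromosome and 1 on an unplaced scaffold. Each peak centre was put in the first fitting class of gene end (within 1 kb), gene body and intergenic. The counts were compared with 1000 random placements of the same widths on the same chromosomes, between the first and the last gene or peak of each. Gaps in the assembly were not left out of that span, which can lower the random counts in genes.

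Each peak was assigned to the nearest protein-coding gene, with a distance of 0 inside a gene, if that gene lay within 100 kb. This held for 3194 peaks (87.2%). The number of list members with a peak was compared with 10000 random gene lists of the same size, matched in 10 bins of the length of sequence nearest to each gene. All 438 members, 398 different genes, were found in the gene table. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 15 lists or the 3 classes, and the threshold was 0.05. The difference in median width was tested with 100000 permutations, and shares of 2 lists with Fisher's exact test on unshared members, adjusted over 14 lists compared with the neurogenic list. Shares with a peak at a gene's own ends were compared for 2 lists by the same test, unadjusted.

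Named genes were those nearest to the 15 widest peaks, up to 4 members per list with the widest peaks, the 5 genes with the most peaks (Slc39a11, Tle3 and Ttc29 tied at 7, taken in alphabetical order), and always Atoh7, Pou4f2, Isl1, Pou4f1, Neurog2, Neurod1, Dll1, Hes5, Hes6, Otx2 and Crx. A further gene that the rule names is not reported here. Further names were chosen after their values were seen.

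Alternatives set beforehand were a distance of 5 kb, protein-coding genes only, any overlap of 1 bp, nearest genes within 10 kb, any peak within 50 kb, and Fisher's exact test without matching. Added after the data were seen were the wider 50% of peaks, peaks moved by a random 50 to 500 kb, matching in 50 bins, lists without members shared with the neurogenic list, peaks more than 5 kb from any gene end or only those within 1 kb of one, and peaks without those at Cwc22 and Gse1. Moved peaks keep each peak in its neighbourhood, so a peak in a long gene often stays in it.

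The scripts were tested on simulated data. Random peaks gave 1 call in 300 list tests, and 60 of 60 lists given extra peaks in 50% of members were called. The list tests were not tried on random peaks that gather at gene ends, as the real peaks do. Random peaks gave 1 call in 20 tests at gene ends, and a set fold of 3.92 was found as 3.88. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.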

Results

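The study profiled where the transcription factor Atoh7 sits in the genome of the developing mouse retina at embryonic day 14. Atoh7 is a basic helix-loop-helix (bHLH) protein made by neurogenic progenitors, and retinas without it lose most retinal ganglion cells, the neurons whose axons form the optic nerve. The assay was CUT&RUN, in which an antibody directs a nuclease to cut and release the DNA next to the bound protein. The labels describe 3 libraries of C57Bl6/J retina, 2 made with an Atoh7 antibody and 1 made with control IgG. The values analysed were a single list of 3668 peaks on the mm10 build, each with its position and width. The median peak was 381 bp wide (quartiles 269 and 486 bp), and the peaks covered 1474 kb in total. The list carries no value per library and no peak height, so library depth is unknown, replicates could not be compared, and the IgG background is not analysed here. Each p-value below refers to the placement of peaks within this one list and not to spread between animals.

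The first question was which genes lie at the Atoh7 peaks. Genes of neurogenic progenitors, the cells leaving the cycle to become neurons, held peaks far more often than other genes. Of 28 such genes, 22 held a peak (78.6%, 95% Wilson interval 60.5 to 89.8%), against 3.51 in random gene lists matched for the sequence around each gene, a 6.27-fold excess. These 22 genes held 52 peaks, and 15 of them held more than 1. The members with the widest peaks were Btg2, an antiproliferative gene, with 3 peaks, Gadd45a and Gadd45g, stress-responsive growth arrest genes, with 5 peaks each, and Srrm4, a regulator of neuronal microexon splicing, with 3. The widest peaks of Btg2, Gadd45a and Gadd45g were centred 11.5, 12.2 and 72.3 kb from the genes. Members without a peak included Sox4 and Sox11, transcription factor genes of differentiating neurons. A gene was said to hold a peak when it was the nearest protein-coding gene to the peak centre, within 100 kb, and by this definition 2403 of 21631 genes (11.1%) held at least 1. The two-sided permutation p for the list was 0.00020, the smallest that 10000 random lists can give, and 0.0010 after Benjamini-Hochberg adjustment over 15 lists. The excess was 3.15-fold against peaks moved by a random 50 to 500 kb (adjusted permutation p = 0.00999) and 3.17-fold for any peak within 50 kb of a gene (adjusted permutation p = 0.0015).

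Genes of the Notch pathway, through which nascent neurons restrain their neighbours, also held peaks in excess, in 14 of 28 members against 3.70 in matched lists (3.79-fold, adjusted permutation p = 0.0010). Among the widest were those at the ligand genes Dll1 (4 peaks) and Dll4 (2 peaks), at Mfng (2 peaks), which encodes a glycosyltransferase acting on Notch, and at Maml3 (5 peaks), which encodes a co-activator of Notch transcription. Named after the values were seen, Rbpj, the DNA-binding partner of activated Notch, held 5 peaks and Notch1 held 3. bHLH factors and their partners held peaks in 18 of 34 members against 4.24 (4.24-fold, adjusted permutation p = 0.0010), among them Atoh7 itself with 4, and Neurod1, Hes6 and Tcf12, a dimer partner of tissue-restricted bHLH proteins, with 2 each. Both lists share members with the neurogenic list. Without the shared members, 8 of 22 Notch genes (2.46-fold, adjusted permutation p = 0.033) and 10 of 25 bHLH genes (2.93-fold, adjusted permutation p = 0.0070) held a peak. The Notch excess was 2.33-fold against moved peaks and the bHLH excess 2.55-fold for any peak within 50 kb, both past the threshold. From peaks more than 5 kb from any gene end, neither list passed it (Notch 2.89-fold, adjusted permutation p = 0.061, and bHLH 2.22-fold, adjusted permutation p = 0.28).

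At single loci, peaks lay close to several genes of the neurogenic programme. The Atoh7 gene (chromosome 10, 63099785 to 63101280) had a peak at 63099416 to 63099997 that overlapped its low-coordinate end, with its centre 79 bp outside the gene. A second peak was centred 1.37 kb away, and a pair of further peaks at 63089274 to 63089649 and 63090148 to 63090681 were centred 10.3 and 9.37 kb away, in intergenic sequence. Neurog2, a proneural bHLH gene, had a peak on chromosome 3 at 127632532 to 127632854, centred 40 bp from the gene. Neurod1, a bHLH gene of differentiating neurons, had peaks centred 297 bp and 2.57 kb from the gene on chromosome 2. Hes6, a bHLH gene expressed in differentiating neurons, had a peak inside the gene and another centred 245 bp outside it, on chromosome 1 between 91413150 and 91414525. Dll1 had a peak inside the gene on chromosome 17 at 15371885 to 15372227 and others centred 2.06, 4.69 and 23.96 kb away. Hes5, a Notch effector, had a peak centred 2.09 kb from the gene.

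**Figure D1:**
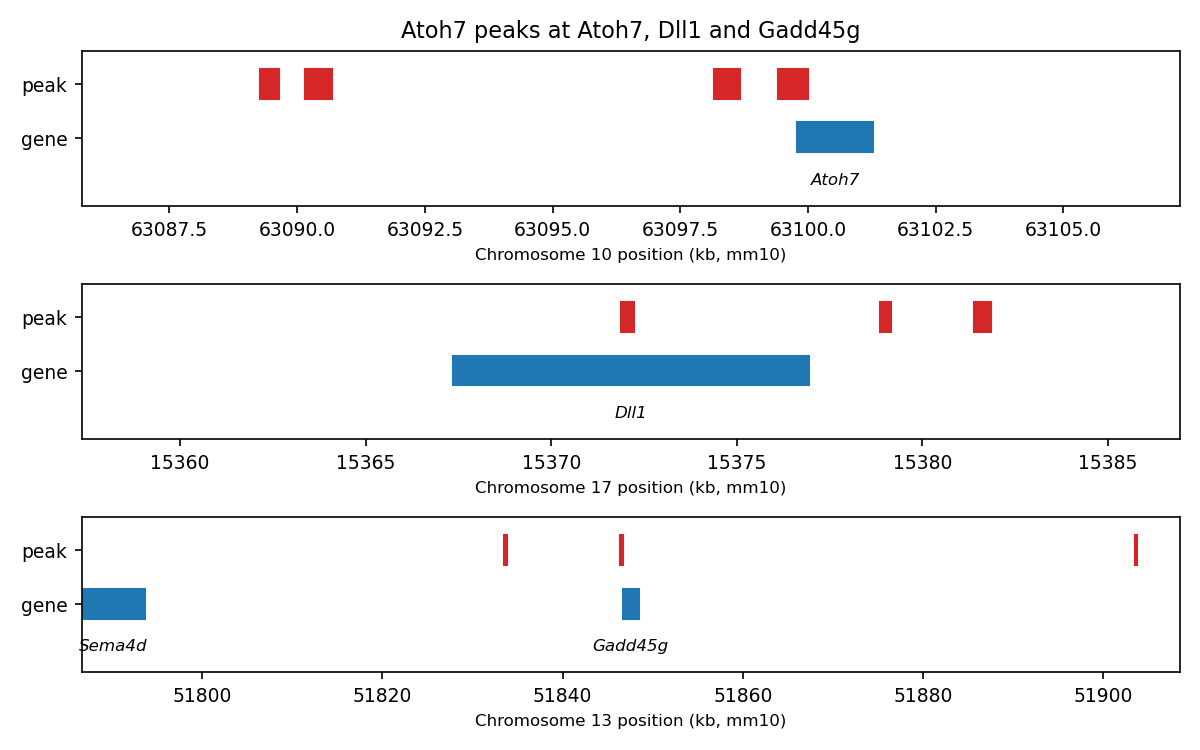
Peaks of the list (red) and protein-coding genes (blue) along mm10 at Atoh7 on chromosome 10, Dll1 on chromosome 17 and Gadd45g on chromosome 13, with position in kb on each horizontal axis. The Atoh7 window shows all 4 peaks of that gene, while the windows of Dll1 and Gadd45g leave out the peaks that lie farther from the gene.

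Retinal ganglion cell factors and markers held peaks in 14 of 30 members against 5.85 in matched lists (2.39-fold, adjusted permutation p = 0.0036). The genes with the widest peaks were Rbpms, a pan-ganglion-cell RNA-binding protein, with 1 peak in the gene body, Tubb3, a neuronal tubulin, with 1, Eya2, a transcriptional co-activator, with 2, and Rbfox3, the neuronal splicing factor known as NeuN, with 2. Pou4f1, a POU-domain factor of ganglion cells, had a peak on chromosome 14 at 104468039 to 104468441, centred 122 bp from the gene. The factors Pou4f2 and Isl1, which are needed for ganglion cell development, held no peak. The nearest peak to Isl1 (chromosome 13, 116298270 to 116309688) lay 205 kb away. The nearest to Pou4f2 (chromosome 8, 78433009 to 78436647) lay 84.0 kb away, inside Ttc29, to which 7 peaks were assigned. The share of ganglion cell genes with a peak was below that of the neurogenic list (14 of 30 against 22 of 28, two-sided Fisher's exact test, adjusted p = 0.020). The excess did not pass the threshold when each peak was moved by a random 50 to 500 kb as the comparison (1.51-fold, adjusted permutation p = 0.11), or from peaks within 1 kb of any gene end alone (2.93-fold, adjusted permutation p = 0.22).

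Genes of other retinal neurons held peaks too. Amacrine and horizontal cell genes did so in 14 of 28 members against 4.16 (3.37-fold, adjusted permutation p = 0.0015), and against moved peaks the excess was 2.09-fold (adjusted permutation p = 0.024). The widest peaks were held by Lhx1, a horizontal cell homeobox gene (1 peak), and Slc32a1, the vesicular GABA and glycine transporter (2 peaks). These were centred 53.4 kb from Lhx1 and 15.9 kb from Slc32a1. Next came Ebf2 (2 peaks) and Foxn4, a forkhead gene needed for amacrine and horizontal cells (1 peak). Photoreceptor genes held a peak in 10 of 28 members against 3.46 (2.89-fold, adjusted permutation p = 0.0050), with the widest at Otx2 (1 peak, centred 48.0 kb from the gene), Casz1 (5 peaks), Prom1 (1 peak) and Neurod1 (2 peaks). Otx2 encodes the homeodomain factor that starts photoreceptor fate, while Crx, which acts after it, held no peak, the nearest being 218 kb away. Any peak within 50 kb of a photoreceptor gene, whether or not another gene was nearer, gave 1.43-fold (adjusted permutation p = 0.35), and peaks within 1 kb of any gene end alone gave 1.64-fold (adjusted permutation p = 0.90). Without members shared with the neurogenic list, 10 of 24 amacrine and horizontal cell genes (2.72-fold, adjusted permutation p = 0.016) and 9 of 27 photoreceptor genes (2.67-fold, adjusted permutation p = 0.019) held a peak. Bipolar cell and Muller glia genes, of cells that mostly arise later, did not pass the threshold, with 5 of 26 members against 3.27 (adjusted permutation p = 0.50). The members with the widest peaks there were Nfia, Prdm8, Aqp4 and Dkk3.

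Retinal progenitor genes held a peak in 10 of 28 members against 4.55 (2.199-fold, adjusted permutation p = 0.028). The widest were held by the eye-field homeobox genes Six3 (1 peak), Meis1 (4 peaks), Lhx2 (1 peak) and Pax6 (2 peaks). These were centred 4.3 kb from Six3, inside Meis1, 34.5 kb from Lhx2 and 8.37 kb from Pax6. This excess did not pass the threshold against moved peaks (1.46-fold, adjusted permutation p = 0.30), for nearest genes within 10 kb (2.19-fold, adjusted permutation p = 0.069), for any peak within 50 kb (1.81-fold, adjusted permutation p = 0.065) or from peaks more than 5 kb from any gene end (1.40-fold, adjusted permutation p = 0.86) or within 1 kb of one (1.59-fold, adjusted permutation p = 0.90). Axon guidance genes, whose products steer ganglion cell axons among others, held a peak in 16 of 40 members against 9.51 (1.68-fold), which did not pass the threshold in the two-sided permutation test (adjusted p = 0.054). Under 4 other settings it did, with folds from 1.70 to 3.62. It did not against moved peaks (1.12-fold, adjusted permutation p = 0.73), with matching in 50 bins (1.41-fold, adjusted permutation p = 0.17), from peaks more than 5 kb from any gene end (1.82-fold, adjusted permutation p = 0.081) or from peaks within 1 kb of one (1.05-fold, adjusted permutation p = 1). The members with the widest peaks were the netrin receptor gene Unc5c (2 peaks), the ephrin receptor gene Ephb1 (1 peak), the secreted repellent gene Slit1 (8 peaks) and its receptor gene Robo2 (5 peaks).

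Lists for other tissues and for general functions served as a comparison. No member held a peak among 26 endothelial, microglial and blood genes (3.44 in matched lists, adjusted permutation p = 0.061) or among 28 liver genes (2.89 in matched lists, adjusted permutation p = 0.12). Skeletal muscle genes held a peak in 4 of 28 members against 2.77 (adjusted permutation p = 0.64), these being Cacna1s, Myh3, Mef2c and Tnnt1. Retinal pigment epithelium and lens genes did so in 2 of 26 against 3.02 (adjusted permutation p = 0.79), these being the lens genes Crybb2 and Bfsp1. Cell cycle genes gave 6 of 30 against 3.22 (adjusted permutation p = 0.21). The widest peaks were held by the phosphatase gene Cdc25b, the S-phase regulator gene E2f1, Btg1 and the cyclin gene Ccne1. Those of Btg1 and Ccne1 were centred 23.8 and 36.8 kb from the genes. Ribosomal protein genes, active in every cell, held a peak in 6 of 30 members against 1.70 (3.53-fold, adjusted permutation p = 0.028). The widest were held by Rpl4, Rps19, Rplp1 (centred 51.0 kb from the gene) and Rpl10a. That excess did not pass the threshold against moved peaks (2.45-fold, adjusted permutation p = 0.070), for nearest genes within 10 kb (3.12-fold, adjusted permutation p = 0.069), for any peak within 50 kb (1.56-fold, adjusted permutation p = 0.16) or by Fisher's exact test without matching (1.80-fold, adjusted p = 0.17). The ribosomal excess did pass with the wider 50% of peaks (6.44-fold, adjusted permutation p = 0.0025) and with matching in 50 bins (3.53-fold, adjusted permutation p = 0.019). It also passed from peaks within 1 kb of any gene end (4.50-fold, adjusted permutation p = 0.033). From peaks more than 5 kb from any gene end, 0 of 30 ribosomal protein genes held a peak, where matched lists gave 0.304, too few for a deficit to be seen. In all, 8 of 15 lists held peaks in excess and none in deficit by adjusted permutation p, with 1 in deficit at an unadjusted permutation p under 0.05 and 0 by Fisher's exact test without matching.

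**Figure D2:**
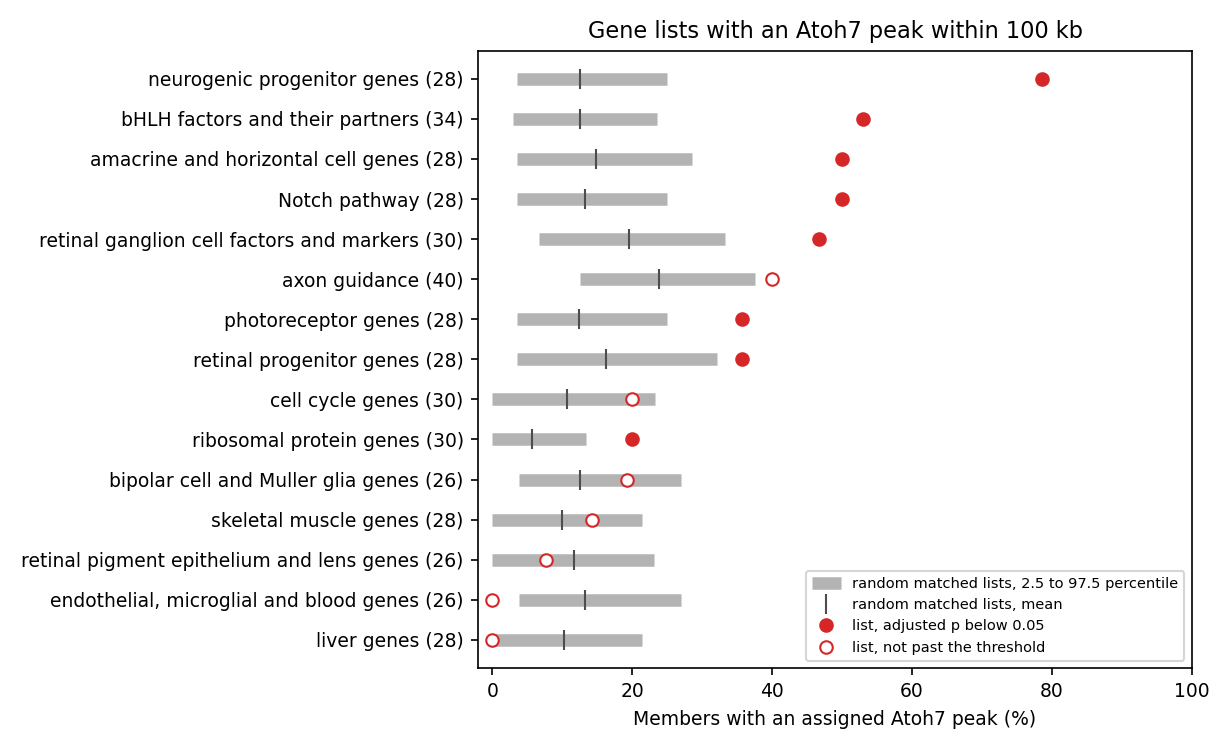
Share of the members of each of 15 gene lists that hold a peak (points, in %), with the number of members in brackets, against the mean (tick) and the central 95% range (grey bar) of 10000 matched random lists. The neurogenic progenitor list lies farthest to the right at 78.6%, and filled points mark the 8 lists with an adjusted p below 0.05.

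The second question was where peaks lie relative to genes. Peaks gathered at gene ends and were scarce between genes. Of the 3662 peaks on chromosomes 1 to 19 and X, 970 (26.5%, 95% Wilson interval 25.1 to 27.9%) were centred within 1 kb of the start or finish of an annotated gene, against 6.40% of randomly placed intervals of the same widths (4.14-fold). A further 1693 peaks (46.2%) lay elsewhere inside a gene, against 45.1% of random intervals (1.02-fold), and 999 (27.3%) lay between genes, against 48.5% (0.563-fold). Ends of protein-coding genes had the highest excess, with 795 peaks against 115 (6.90-fold), and ends of long noncoding RNA genes had 244 against 72.03 (3.39-fold). A peak near ends of several kinds of gene was counted for each kind. Adjusted permutation p was 0.0030 for gene ends and for intergenic sequence and 0.18 for gene bodies, the unadjusted 0.0020 being the smallest that 1000 placements can give. Within 5 kb of a gene end the excess was 1.83-fold (43.7% of peaks against 23.9%). Against peaks moved by a random 50 to 500 kb, gene ends kept a 3.16-fold excess, while gene bodies turned to a deficit (0.863-fold, adjusted permutation p = 0.0020).

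**Figure D3:**
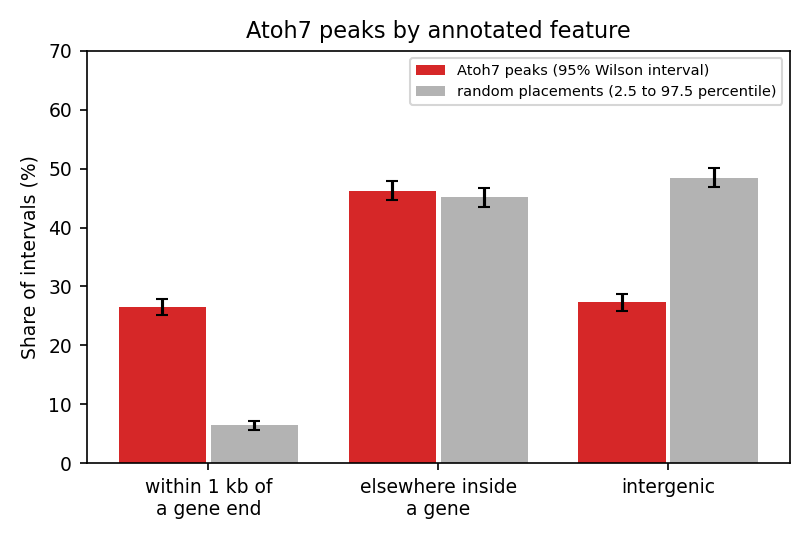
Share of peaks (red, with 95% Wilson intervals) and of random placements (grey, with the central 95% range of 1000 placements) in each annotated class, in % of 3662 intervals. Peaks within 1 kb of a gene end make up 26.5% against 6.40% at random, and intergenic peaks 27.3% against 48.5%.

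Several of the widest peaks were centred inside genes, which was common in the whole list (46.2% in gene bodies away from gene ends) and was not tested. Of the 15 widest, 3 were on the mitochondrial chromosome. The widest of the others (1612 bp, chromosome 11, 86851476 to 86853087) had Dhx40 as its nearest protein-coding gene, at 44.4 kb. That peak covered the miRNA gene Gm51288 and was centred 323 bp from its end. Peaks of 1365 to 1162 bp were centred inside Phc2, a Polycomb gene, Cdc25b, Ctif, Fam83f, Rassf4, Ankdd1a, Msi1, which encodes a neural RNA-binding protein of progenitors, and Coro1c, an actin regulator. Others in that range were centred outside their nearest protein-coding genes Coq8b, Grasp and Cwc22, at 207 bp, 2.78 kb and 59.5 kb. The Grasp peak was centred 180 bp from an end of the long noncoding RNA gene AU021063. The Coq8b peak overlapped the end of that gene and also Numbl, a Notch pathway gene counted without a peak because Coq8b lay nearer to the peak centre. Peaks within 1 kb of a gene end were narrower than others, with medians of 365 and 386 bp (difference -21 bp, two-sided permutation p = 0.0033), but with 5 kb the difference was -11 bp (permutation p = 0.074). The genes with the most peaks were Gse1 with 27, Cwc22, a splicing factor gene, with 17, Auts2, a neurodevelopmental gene, with 9, Slit1 with 8, and Slc39a11, a zinc transporter gene, with 7. These counts are not corrected for gene length, which was 353, 65.2, 1106, 149 and 405 kb in that order. Across the Cwc22 peaks, 27.9% of the running numbers in the peak names were present in the list, against 51.1% over all peaks.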

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

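The peaks on the mitochondrial chromosome were singled out after the list had been seen, and no test was run on them. This is signal in a part of the list that the comparisons leave out: 5 peaks, covering 7459 bp of that chromosome. The widest, at 1792 to 4814, was 3023 bp long and ran from the ribosomal RNA gene mt-Rnr2 to ND2, and the next, at 11523 to 13957, was 2435 bp long and ran from ND4 to ND6. The peak at 5 to 1351 (1347 bp) covered mt-Rnr1, and the last 2 (315 and 339 bp) lay in COX1. The IgG library gives no value to set beside them here.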

How the results depend on the processing

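The settings chosen after the data were seen were the wider 50% of peaks, moved peaks, 50 bins, lists without shared members, peaks more than 5 kb or only those within 1 kb from any gene end, peaks without those at Cwc22 and Gse1, and both distances for peak width. Of 154 alternative values with a test, 127 kept their direction and side of the threshold. These values are not independent, and some could hardly change. Lists that share no member with the neurogenic list are the same without shared members, and the gene-end result entered both as a share and as a class. The number of lists in excess, 8, ranged from 4 to 9 over the settings, and the number in deficit was 0 in each. The causes of the changes below were not tested. Against moved peaks, folds were 0.863 for gene bodies, 1.51 for ganglion cell genes, 1.46 for retinal progenitor genes, 2.45 for ribosomal protein genes, 0.970 for bipolar cell and Muller glia genes and 0.932 for muscle genes, and 5 lists instead of 8 were in excess. With nearest genes within 10 kb, folds were 2.19 for retinal progenitor, 3.12 for ribosomal protein and 2.02 for axon guidance genes. With any peak within 50 kb they were 1.81, 1.56 and 1.70, and 1.43 for photoreceptor genes. Fisher's exact test without matching gave 1.80 for ribosomal protein and 3.62 for axon guidance genes. The wider 50% of peaks gave 2.13 for axon guidance genes and 0 for muscle genes. Axon guidance genes passed the threshold in each of these last 4 settings. In the settings so far, the calls lost were those of ganglion cell genes (moved peaks), photoreceptor genes (any peak within 50 kb), retinal progenitor genes (moved peaks, 10 kb, 50 kb) and ribosomal protein genes (moved peaks, 10 kb, 50 kb, Fisher's exact test). From peaks more than 5 kb from any gene end, 4 lists were in excess, and the calls were lost for Notch (2.89), bHLH (2.22), retinal progenitor (1.40) and ribosomal protein genes (0). From peaks within 1 kb of any gene end, 5 lists were in excess, the calls were lost for ganglion cell (2.93), retinal progenitor (1.59) and photoreceptor genes (1.64), and folds were 0.911 for bipolar cell and Muller glia genes and 0.786 for cell cycle genes. The neurogenic list stayed past the threshold in each setting run on it, with folds from 3.15 against moved peaks to 11.1 from peaks within 1 kb of any gene end. The width difference at gene ends was -11 bp with 5 kb. Not run were the E-box and strength settings and leaving out a replicate. No paired analysis was possible because the list has no values per library. Depth is unknown, so its effect on which sites were called is open.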

Other observations

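Set before the data were seen were the fold of ribosomal protein genes over matched genes and the test on skeletal muscle genes. The other tests in this part, including the comparison of peaks at genes' own ends, were chosen afterwards. Gene families that share a symbol root, 257 of them with at least 10 members, were compared with matched genes. Olfactory receptor genes (Olfr) held a peak in 1 of 1110 members, Olfr223, against 79.2 in matched lists, and vomeronasal receptor genes (Vmn) in 0 of 355 against 34.8 (adjusted permutation p = 0.017 for each). Voltage-gated calcium channel genes (Cacna) held a peak in 10 of 14 members against 3.02 (3.31-fold, adjusted permutation p = 0.017), among them Cacna1a, Cacna1b and Cacna1c, but with matching in 50 bins the excess was 2.77-fold and the adjusted permutation p 0.086. The olfactory and vomeronasal families passed the threshold in both (0.026 for each in 50 bins). Each member was matched separately, so members that are neighbours on a chromosome counted as independent. Moved peaks were not tried on families, so a peak-poor neighbourhood cannot be told apart from a deficit at these genes.

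Small RNA genes also lay at peaks. Peaks that lay at ends of protein-coding genes too were not left out of the counts below. The excesses are thus not shown to be particular to small RNA genes. Ends of genes classed as snRNA in the gene table had 13 peaks within 1 kb against 3.07 in random placements (4.23-fold). Among them were Rnu11 and Rnu12, of the minor spliceosome, and Rnu3b1, Rnu3b3 and Rnu3b4. Some of these peaks lay close together, on chromosome 11 between 87443350 and 87463038 and on chromosome 1 between 72226364 and 72255831. Random placements put each peak separately and do not reproduce such groups. Ends of miRNA genes had 13 against 3.20 (4.06-fold; 2.36-fold against moved peaks, adjusted permutation p = 0.016), and Mir183 and Mir96, of a microRNA cluster expressed in sensory cells, shared a peak on chromosome 6 at 30169155 to 30169399. Pseudogene ends had 11 peaks against 40.2 (0.274-fold), and the adjusted permutation p was 0.0040 for each of these 3 classes. Ends of genes classed in the gene table as snoRNA (5 against 3.77) or tRNA (2 against 0.985) did not pass the threshold. These classes were taken as given and were not checked gene by gene. Peaks assigned to neurogenic progenitor genes were wider than the others, with medians of 441 and 380.5 bp (52 and 3610 peaks, permutation p = 0.034).

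The excess of peaks at neurogenic progenitor genes was set against 3 technical explanations. A peak-dense neighbourhood is argued against as the whole cause by moving each peak by 50 to 500 kb: over 1000 moves, at most 14 neurogenic genes held a peak (median 7), against 22 observed. Open ends of any active gene are argued against as the whole cause at neurogenic genes only by tests chosen after the data were seen. Peaks more than 5 kb from any gene end still gave a 5.12-fold excess of them (10 of 28 members, adjusted permutation p = 0.0030), and a peak within 1 kb of the gene's own ends was found at 11 of 28 of them (39.3%) against 13.3% of 30 ribosomal protein genes and 0 of 30 cell cycle genes (Fisher's exact test, p = 0.036 and 9.4e-05). The comparison set beforehand did not decide. Ribosomal protein genes had a 3.53-fold excess over matched genes, below the 6.27-fold of neurogenic genes but not as far below as had been asked. A part played by gene ends therefore stays open. Chromatin open to bHLH factors of any tissue was looked at with skeletal muscle genes. Of these, 14.3% held a peak (95% Wilson interval 5.70 to 31.5%), below the 78.6% of the neurogenic list. Peaks thus did not gather at muscle genes as they did at neurogenic genes. No chromatin data were used here, so this share cannot decide about retinal chromatin open to other bHLH factors at neurogenic genes. How far open chromatin at gene ends may contribute, and what an IgG list would show, stay open, and no biological explanation was tested, since the list compares no groups.

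Gse1 and Cwc22 held clusters of peaks. The fullest 150 kb window of the list held 17 peaks, against 6 in the highest of 200 random draws. That is as many as the Cwc22 cluster held in 139 kb. The Gse1 peaks, 27 over 341 kb, were not set against random draws on their own. One candidate explanation is a segment of raised background in the library behind the peak numbers, if those numbers count calls made before filtering. It predicts many numbers and few of them present. At Cwc22, 61 numbers fell in 139 kb (43.8 per 100 kb, against 0.275 over all chromosomes) and 27.9% were present (95% Wilson interval 18.2 to 40.2%), below the 51.1% of the whole list (Fisher's exact test against the rest, p = 0.00027), which goes with that explanation. At Gse1, numbers were also dense (10.6 per 100 kb), and 75% of 36 were present (58.9 to 86.2%). Gse1 was picked for its many peaks kept, which raises that share by itself, so raised background there stays open. Extra copies of the Cwc22 segment in these mice relative to the assembly stay open and untested.

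The X chromosome held 37 peaks, or 2.17 per 10 Mb, against 10.6 to 21.7 on the 19 autosomes. Per 100 protein-coding genes it held 3.83 against 10.3 to 24.3. Of the peak numbers spanned on X, 35 of 96 were present (36.5%, 95% Wilson interval 27.5 to 46.4%), against 51.2% on autosomes (Fisher's exact test, p = 0.0053).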
